A study of Mus musculus and Homo sapiens with 17 samples.

How the data were processed

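RNA sequencing was available for 17 libraries. Of these, 9 came from mouse hepatocytes, 6 from primary human hepatocytes (PHH) and 2 from the human hepatoma cell line HepG2. Per the labels, 3 human libraries were prepared with the TruSeq kit and the other 14 with the LM-Seq protocol, and libraries were sent for sequencing under submission numbers 353, 365, 421 and 427. The doses of the inhibitors were not given in the sources used here.

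Per the submitters' processing notes, reads were processed with CASAVA 1.8.2, Bowtie 0.12.9 and RSEM 1.2.3 and the genome builds were hg19 and mm10; the annotation was not given in the sources used here. The authors deposited expected counts per gene, as RSEM estimates them, in 1 table for each species, and the deposited values are not normalised. The authors also deposited TPM, transcript abundance scaled to the same total in each library, for the same genes, and each TPM column summed to between 999999.3 and 1000001.8. Expected counts were rounded to whole numbers before any test. The mouse count table held 20308 genes, and in the last 1224 of them the values stood 2 columns to the left of their headings. In those genes the pattern of zero and non-zero counts matched the TPM 2 columns to the right in 100% of genes and the TPM of the same heading in 89.3% to 95.92%. They were left out of every count test, which used the remaining 19084 genes. In TPM, where nothing was shifted, the genes left out made up 1.06% to 2.12% of a library, and 524 of them reached a TPM of 5 in a library. The human tables held 19084 genes.

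Samples were grouped by their labels. Each condition had 1 library. In mouse, U0126, LY294002 and rapamycin were crossed in full, so each inhibitor was present in 4 of the 8 cultured libraries and absent from 4. The effect of each inhibitor was tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test on an additive model of all 3 inhibitors (4 residual degrees of freedom), with TMM scaling (CPM in the text are counts scaled to the TMM-adjusted library total), the default filter on low counts and Benjamini-Hochberg adjustment at 0.05. Each pairwise interaction was added to that model in turn (3 residual degrees of freedom). The change in culture was tested between the modelled vehicle level and the uncultured library, with all 9 mouse libraries in the fit. The 1 uncultured library adds no spread and was assumed to vary like the 8 cultured libraries. A common effect of U0126 in the human libraries of submission 421 was fitted with the labelled kind of cell as a block, which left 1 residual degree of freedom. The source names number the mouse libraries but do not say that they came from separate animals, so p-values measure only the spread between these libraries, which may be technical. These choices, the gene lists and the rule for naming genes were made before the data were examined.

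The other human comparisons had 1 library a side and no test. They are given as TMM-scaled log2 ratios with a prior count of 2, counted where a gene reached 5 CPM in either library and the ratio was at least 1 or at most -1 on the log2 scale. Ratios of single genes carry exact 95% counting intervals. Where a library or a whole group was at 0, the fold is a lower bound against a floor of 3 counts per library. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

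For each species 32 gene lists were fixed: plasma proteins, drug-metabolising cytochromes P450, conjugation enzymes, bile acid and transport genes, urea cycle and amino acid enzymes, gluconeogenesis and glucose genes, hepatocyte transcription factors, complement and coagulation factors, fetal liver genes, dedifferentiation and cytoskeleton genes, cell cycle genes, acute phase genes, immediate early and stress genes, targets of ERK, TGF-beta, FOXO, ATF4, NRF2, AHR, CAR/PXR and PPAR-alpha (fatty acid oxidation), glycolysis, oxidative phosphorylation, sterol synthesis, lipogenesis, ribosome biogenesis, lysosome and autophagy genes, and markers of cholangiocytes, macrophages, stellate cells and fibroblasts, endothelial cells, and lymphoid and erythroid cells. In mouse, lists with at least 3 measured members (31) were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of each effect, with camera's estimated correlation and fry beside it. In human pairs, the median log2 ratio of a list is given with its percentile among 10000 random lists of equal size matched on mean expression in 20 bins. The 200 genes most raised and the 200 most lowered in culture were tested in the same way under each inhibitor. In mouse they were ranked by the mean of all 8 cultured libraries against the uncultured one, whose error is independent of the inhibitor contrasts. That mean still holds part of each inhibitor's own effect.

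Genes were named by a fixed rule. In tested comparisons these were the 8 most raised and 8 most lowered by log2 fold change among genes past the threshold with a mean of at least 10 CPM, which for an inhibitor also changed the same way in all 4 matched pairs. To them were added up to 4 members of each list by smallest p, and Alb, Cyp3a11 (CYP3A4 in human), Hnf4a, Dusp6, Spry4 and Vim always. In untested human pairs they were the 10 highest and 10 lowest ratios with at least 20 CPM and up to 4 members of each list by size of ratio. Sex-linked markers, clone-named, small RNA and ribosomal RNA genes were not named. Other genes are said to be chosen after their values were seen. Mouse positions come from GENCODE M21 (mm10); human positions were not used here.

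Each test was tried on simulated counts drawn from the real means and library sizes, with 200 genes changed 2-fold or 4-fold. For U0126 (9835 genes) 53.1% of the 2-fold and 91.9% of the 4-fold changes were recovered, and 13 of 155 calls were of unchanged genes. For LY294002 (9780 genes) the shares were 48.0% and 88.9%, with 2 of 137 calls false. For rapamycin (9801 genes) they were 41.4% and 91.6%, with 5 of 133. For the interactions, U0126 with LY294002 (9836 genes) gave 3.0% and 53.0% with 8 of 64 false, U0126 with rapamycin (9799 genes) 4.0% and 49.5% with 10 of 62, and LY294002 with rapamycin (9831 genes) 6.2% and 56.1% with 7 of 68. The culture change (9578 genes) gave 1.1% and 23.9% with 0 of 22, and the common human effect (10462 genes) 1.1% and 24.0% with 4 of 28. Of 20 sets of 30 genes in the simulated U0126 effect (9835 genes), the planted set was called by camera and by fry and 0 others were. Genes were drawn independently of each other, so this trial cannot tell how camera behaves where the genes of a list are correlated. In a simulated human pair (10071 genes), 200 of 200 4-fold changes and 32 of 9871 unchanged genes were counted, and the raised set lay at percentile 100. Both libraries of that pair were drawn from 1 profile with counting error only. These shares therefore leave out variation between cultures, kits and submissions.

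The alternatives tried were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-trend on log2(TPM + 1), robust dispersions, no covariates, all pairwise interactions in the model, each inhibitor alone against vehicle, and each library left out in turn. The culture change was also taken against the mean of the cultured libraries. Human ratios were repeated with prior counts of 0.5 and 5, with library size only, with a minimum of 20 CPM and on TPM. Culture sets of 100 and 500 genes were tried. Leaving out both libraries that received LY294002 with rapamycin, limma-trend on TPM with the shifted genes included, and matched pairs as a block were chosen after seeing the data. Tables were read with Python 3.11.15 and pandas 2.3.3 and drawn with matplotlib 3.10.9.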

Results

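Gene expression was measured by RNA sequencing in mouse and human liver cells to ask which pathway inhibitors change the state of hepatocytes in culture. Mouse hepatocytes gave 9 libraries: 1 uncultured, 1 after 72 h with vehicle (DMSO), and 1 for each single, paired and triple combination of U0126 (an inhibitor of the kinase MEK), LY294002 (of PI3K) and rapamycin (of mTOR) for 72 h. PHH gave 6 libraries, namely a mixture of lots uncultured and after 24 h, and 1 lot uncultured and after 72 h with DMSO, U0126 or PD0325901, a second MEK inhibitor. HepG2 cells, a hepatoma line, gave 2 libraries, with DMSO (labelled 0 h) and with U0126 (72 h). No condition had a replicate, so each mouse inhibitor was judged from the 4 libraries with it against the 4 without it, which form 4 matched pairs.

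The mouse libraries held 3936427 counts (uncultured), 4621433 (vehicle), 4882197 (U0126), 3984045 (LY294002), 4389274 (rapamycin), 4782618 (U0126 with LY294002), 4569605 (U0126 with rapamycin), 3894513 (LY294002 with rapamycin) and 4179057 (all 3). The human libraries held 8737492 (mixture, uncultured), 8666321 (mixture, 24 h), 15406167 (lot, uncultured), 4192885 (PHH DMSO), 4346985 (PHH U0126), 3296921 (PHH PD0325901), 4080941 (HepG2 DMSO) and 4702858 (HepG2 U0126). A floor of 3 counts, used where a library was at 0, came to 0.195 to 0.91 counts per 1000000 of the unadjusted library totals.

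Among the 5 human LM-Seq libraries, 2 held the transcripts of the other kind of cell. The library labelled PHH DMSO had 2256 TPM of AFP and 2670 TPM of GPC3, transcripts abundant in hepatoma cells, and 0 TPM of CYP2E1, CRP and SAA1, which hepatocytes make. The library labelled HepG2 U0126 had 4.74 TPM of AFP, 1.36 TPM of GPC3, 833 TPM of SAA1 and 493 TPM of VIM. Across 12166 genes, which are not independent replicates, the library labelled PHH DMSO had a Spearman correlation of 0.881 with HepG2 DMSO and 0.757 with PHH U0126. The library labelled HepG2 U0126 had 0.978 with PHH U0126 and 0.705 with HepG2 DMSO. Groups were kept as labelled. AFP, GPC3, DLK1 and CRP were chosen for this check after their values were seen.

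**Figure D1:**
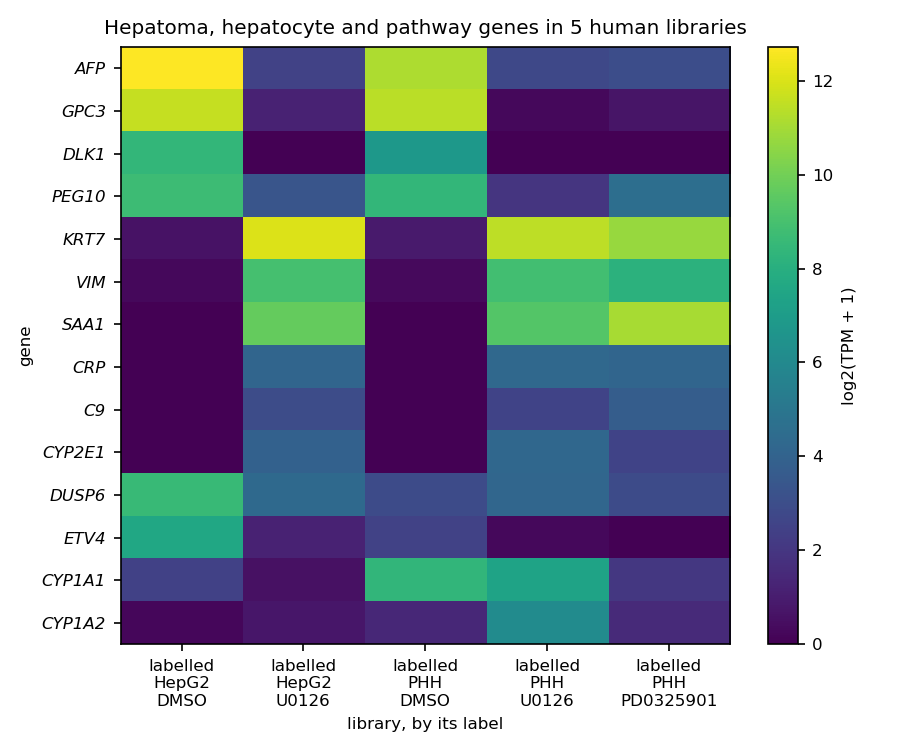
Colour gives log2(TPM + 1) of 14 genes (vertical axis) in the 5 human LM-Seq libraries, named by their labels (horizontal axis). AFP reached 6727 TPM in the library labelled HepG2 DMSO and 2256 TPM in that labelled PHH DMSO, against 4.74 to 7.07 TPM in the other 3. CYP1A1 was at 326 and 167 TPM in the libraries labelled PHH DMSO and PHH U0126, against at most 4.59 TPM in the rest.

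The first mouse comparison asked what 72 h of culture changed. Genes of liver metabolism fell, and genes of the cytoskeleton and the cell cycle rose. Cyp2e1, a cytochrome P450 of the liver (chromosome 7, 140763739 to 140774987), was at 9907 CPM in the uncultured library and 63.5 CPM with vehicle, 156-fold lower (counting interval 140 to 175). Pck1, the first committed enzyme of gluconeogenesis, was 922-fold lower (501 to 1920), and Fabp1, the liver fatty acid binding protein, 447-fold lower (368 to 549). S100a6, a calcium-binding protein of proliferating cells, was at 0 in the uncultured library and at least 404-fold higher with vehicle. In the edgeR fit 3451 of 10573 genes changed, 1651 higher and 1800 lower, and 3121 by at least 2-fold. The spread came from the 8 cultured libraries alone, as there was 1 uncultured library.

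Most groups of liver functions were lower in culture. Of 21 measured plasma protein genes 20 fell (20 adjusted over the list alone, median log2 fold change -1.78, camera adjusted p = 3.98e-08, and adjusted p = 0.268 with an estimated correlation). Alb, which encodes albumin, fell by 1.59 ± 0.36 (SE, edgeR adjusted p = 0.00728, lower in 8 of 8 cultured libraries). Among 19 urea cycle and amino acid enzymes 17 fell (17 adjusted over the list alone, median -3.87, adjusted p = 6.66e-09, and adjusted p = 0.301 with an estimated correlation). Hpd and Agxt of tyrosine and glyoxylate metabolism were 93.8-fold and 59.8-fold lower. Of 21 cytochromes P450 16 fell (16 over the list alone, median -3.08, adjusted p = 3.62e-07, adjusted p = 0.268 with an estimated correlation). The fatty acid oxidation genes fell in 18 of 21 (19 adjusted over the list alone, median -2.88, adjusted p = 1.14e-09, adjusted p = 0.0695 with an estimated correlation). Ehhadh of peroxisomes was among them (-4.29 ± 0.22, edgeR adjusted p = 3.88e-06, lower in 8 of 8 cultured libraries). Bile acid and transport genes fell in 14 of 16 (15 over the list alone, median -3.69, adjusted p = 3.04e-08 and 0.268 with an estimated correlation). Complement and coagulation factors fell in 20 of 23 (21 over the list alone, median -2.13, adjusted p = 2.87e-09 and 0.268). Conjugation enzymes fell in 13 of 22 and rose in 2 (median -2.40, adjusted p = 0.000689 and 0.556). Of 18 hepatocyte transcription factors 13 fell and 1 rose (14 and 1 over the list alone, median -2.11, adjusted p = 9.75e-05 and 0.268). Cebpa was 7.53-fold lower and Foxa2 12.9-fold higher (6.12 to 32.5). Hnf4a, a regulator of hepatocyte identity, fell by 0.95 ± 0.29 (edgeR adjusted p = 0.0288). On TPM Hnf4a lay at 0.065, where the median of all genes lay at 0.92. Spry4 and Cyp3a11 did not pass (-1.07 ± 0.70, adjusted p = 0.259, and -2.26 ± 1.08, adjusted p = 0.132).

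Dedifferentiation and cytoskeleton genes rose in 21 of 27 and fell in 1 (22 and 2 adjusted over the list alone, median 3.08, or 2.98 with members at 0 set to their bound, camera adjusted p = 6.66e-09, and 0.268 with an estimated correlation). Of these, Anxa3, an annexin, was 644-fold higher (220 to 3120), and Vim, an intermediate filament of mesenchymal cells, rose by 2.39 ± 0.56 (edgeR adjusted p = 0.00845, higher in 8 of 8 cultured libraries). Cell cycle genes rose in 9 of 26 (14 over the list alone, median 2.52, or 2.00 with bounds, adjusted p = 0.0002 and 0.594). Markers of cholangiocytes rose in 6 of 10 and fell in 1 (7 and 1 over the list alone, median 2.62, or 2.04 with bounds, adjusted p = 0.0265 and 0.268). Endothelial markers had a median of -1.68 with 1 of 15 lower, Stab2 of sinusoidal endothelium (-2.79 ± 0.55, adjusted p = 0.00297 and 0.268 for the list). Immediate early and stress genes fell in 14 of 16 (14 over the list alone, median -3.10, adjusted p = 3.98e-08 and 0.215). Egr1 was 66.4-fold lower. ERK targets fell in 7 of 18 (7 lower and 1 higher over the list alone, median -0.89, adjusted p = 0.0265 and 0.268). Dusp6, the ERK phosphatase, was 5.97-fold lower (5.43 to 6.57) and lower in 8 of 8 cultured libraries. Oxidative phosphorylation (10 of 19 fell, median -0.74, adjusted p = 0.000164 and 0.421), gluconeogenesis (5 of 12, 6 over the list alone, -1.57, 0.00355 and 0.514), acute phase (11 of 19 fell and 1 rose, -2.02, 0.000477 and 0.268) and FOXO target genes (9 of 17 fell and 1 rose, -1.42, 0.000746 and 0.268) were also called. Not called were TGF-beta targets (median -0.238 but mean 0.402, and camera downward, adjusted p = 0.599), lysosome genes (0.0213 and 0.133, downward, 0.393) and stellate markers (0.417 and 0.590, downward, 0.947). Nor were sterol synthesis (median -0.62, 0.0684), lipogenesis (-0.57, 0.136), ATF4 targets (0.59, 0.203), glycolysis (0.24, 0.801), ribosome biogenesis (0.50, 0.667) and NRF2 targets (0.56, 0.202). The same held for AHR targets (-2.07, 0.203), CAR/PXR targets (-0.70, 0.259), fetal liver genes (0.67, 0.599) and macrophage markers (-0.86, 0.0684). On TPM camera no longer called cholangiocyte markers (adjusted p = 0.311) or oxidative phosphorylation (0.311), and it called AHR targets (0.0187) and macrophage markers (0.000639). Without the 2 libraries that received LY294002 with rapamycin it called sterol synthesis downward (median -0.76, 9 of 19 lower, adjusted p = 0.00875). On TPM, limma called 5937 genes, 5043 of them higher, as the median of all genes then lay at 0.92.

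**Figure D2:**
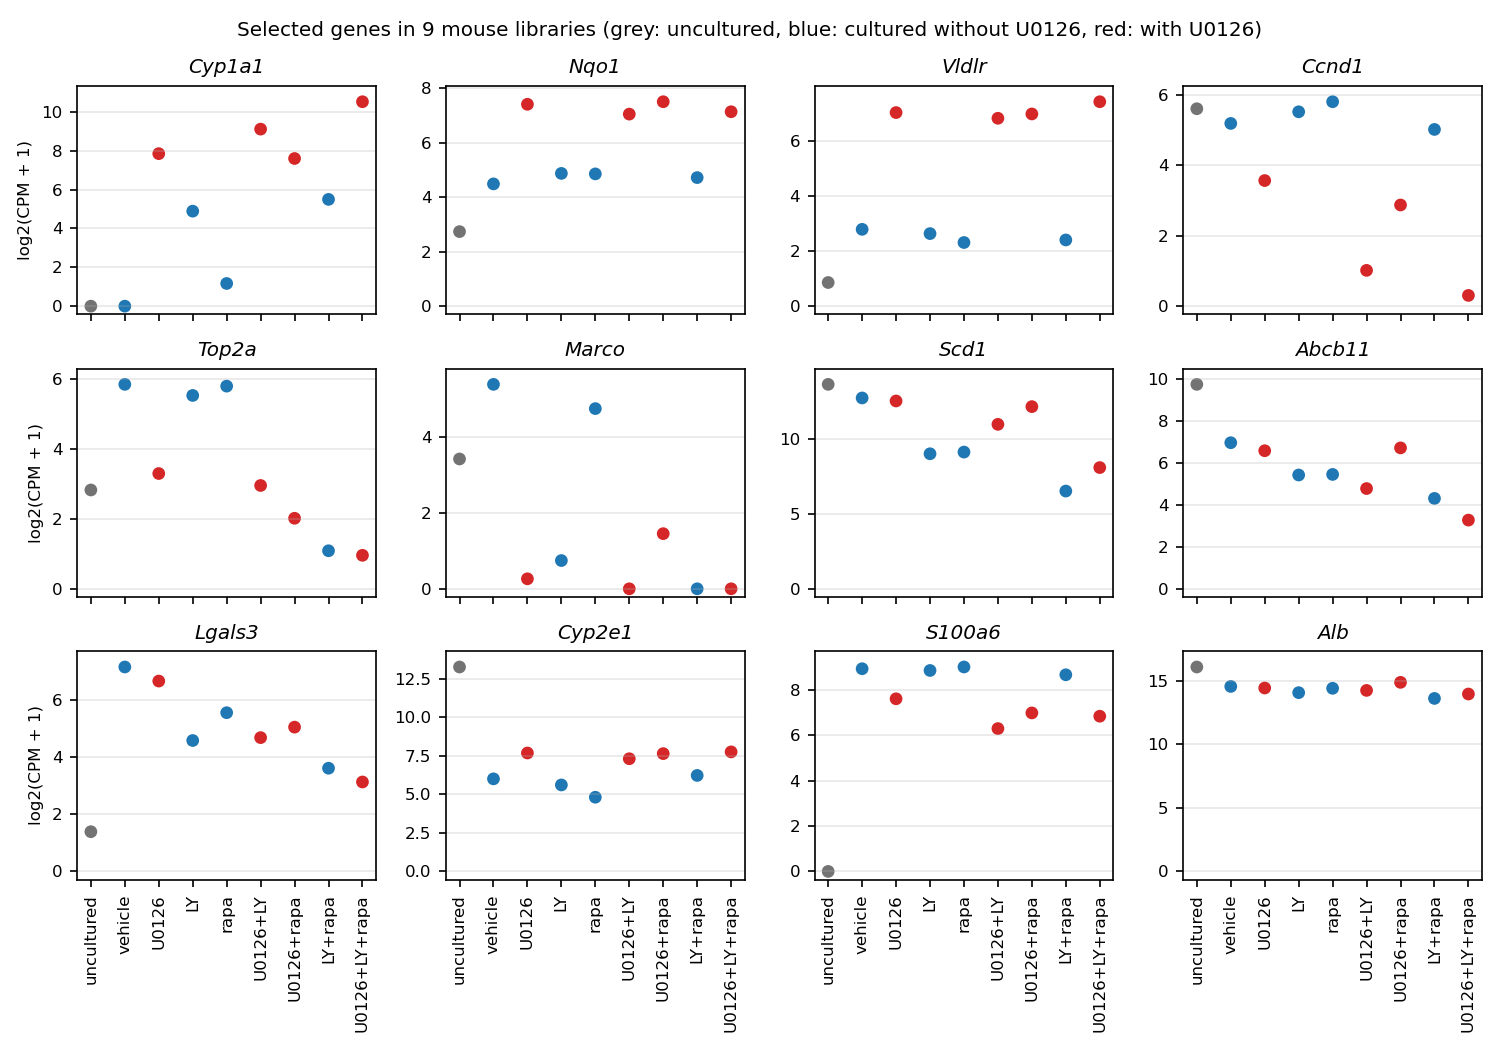
Each point is log2(CPM + 1) of 1 mouse library (vertical axis) for 12 genes in the uncultured, vehicle and inhibitor conditions (horizontal axis, LY, LY294002, rapa, rapamycin); red marks U0126. Cyp1a1 was at 0 in the uncultured and vehicle libraries and averaged 643 CPM in the 4 libraries with U0126. Marco averaged 0.181 CPM in the 4 libraries with LY294002 against 18.2 CPM in the 4 without.

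U0126 asked what blocking MEK does to cultured mouse hepatocytes. Drug-metabolising and antioxidant genes rose, and cell cycle genes fell. Cyp1a1, the classical target of the aryl hydrocarbon receptor (chromosome 9, 57687928 to 57703824), averaged 643 ± 621 CPM (SD, n = 4) with U0126 and 19.7 ± 22.9 CPM without it (log2 fold change 5.71 ± 0.63 SE, edgeR adjusted p = 0.00111, higher in 4 of 4 matched pairs). Vldlr, a lipoprotein receptor (chromosome 19, 27216484 to 27254231), had the smallest adjusted p, with 140.5 ± 25.4 CPM against 5.12 ± 0.93 CPM (4.76 ± 0.22, adjusted p = 7.86e-06, higher in 4 of 4 pairs). Ccnd1, which encodes the cyclin of the G1 phase (chromosome 7, 144929931 to 144939925), averaged 4.87 ± 5.25 CPM against 44.0 ± 11.1 CPM (-3.50 ± 0.55, adjusted p = 0.00635, lower in 4 of 4 pairs). In all, 700 of 9973 genes changed, 358 higher and 342 lower, 438 by at least 2-fold.

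The AHR targets rose in 5 of 7 (5 higher and 1 lower adjusted over the list alone, median 2.58, camera adjusted p = 2.78e-07, and adjusted p = 0.152 with an estimated correlation). Besides Cyp1a1 these included Cyp1a2 (4.73 ± 0.45, adjusted p = 0.000541) and Ugt1a6a, a glucuronosyltransferase (2.81 ± 0.27). NRF2 targets, antioxidant genes, rose in 9 of 17 and fell in 1 (15 and 1 over the list alone, median 0.81, adjusted p = 5.15e-11, and 0.152 with an estimated correlation). Nqo1, a quinone reductase, was among them (164.9 ± 24.8 against 27.4 ± 3.5 CPM, 2.58 ± 0.17, adjusted p = 5.86e-05), as was Srxn1, sulfiredoxin (2.28 ± 0.25, adjusted p = 0.00111). Cytochromes P450 rose in 9 of 21 (14 over the list alone, median 1.14, adjusted p = 5.15e-11 and 0.312), with Cyp2e1 at 1.88 ± 0.28 (adjusted p = 0.00506). Conjugation enzymes rose in 11 of 22 (14 over the list alone, median 1.10, adjusted p = 5.15e-11 and 0.387), with Gsta2, a glutathione transferase, at 2.90 ± 0.18. CAR/PXR targets rose in 7 of 16 (11 higher and 1 lower over the list alone, median 1.17, adjusted p = 3.05e-06 and 0.344), with Alas1 of haem synthesis at 1.57 ± 0.15. Each of these 6 enzymes and Srxn1 was higher in 4 of 4 matched pairs. Cyp2a4 (7.94 ± 0.85) and Ces1f (4.05 ± 0.27) were among the most raised genes, but both, like the Gsta and Ugt1a genes, have near-identical copies and their counts are uncertain.

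Some genes of amino acid and energy metabolism rose. ATF4 targets of the amino acid response rose in 9 of 20 (13 over the list alone, median 0.98, camera adjusted p = 3.72e-10, and 0.312 with an estimated correlation). Slc3a2, an amino acid transporter subunit, was at 1.61 ± 0.15 (adjusted p = 0.000541, higher in 4 of 4 pairs). Urea cycle and amino acid enzymes rose in 4 of 19 (6 over the list alone, median 0.61, adjusted p = 0.000323 and 0.45). Arg1, the last enzyme of the urea cycle, was at 2.18 ± 0.33 (adjusted p = 0.00533, higher in 4 of 4 pairs). Bile acid and transport genes rose in 2 of 14 (5 over the list alone, median 0.82, adjusted p = 0.00588 and 0.45). Fatty acid oxidation genes rose in 4 of 21 (6 over the list alone, 0.46, 0.00809 and 0.312), and glycolysis genes in 3 of 18 with 1 lower (6 and 1 over the list alone, 0.33, 0.0126 and 0.447). Pkm, the pyruvate kinase of proliferating cells, led these (2.12 ± 0.20). Oxidative phosphorylation (1 of 19 higher, median 0.22, adjusted p = 8.99e-05 and 0.431) and sterol synthesis (0 of 19, 0.30, 0.0155 and 0.604) were called with few or no members past the edgeR threshold.

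Cell cycle genes fell in 20 of 26 (25 adjusted over the list alone, median -2.29, camera adjusted p = 5.53e-15, and 0.387 with an estimated correlation). Among them were Top2a, a topoisomerase of dividing cells (-3.03 ± 0.65, edgeR adjusted p = 0.024), and Mcm5, a replicative helicase subunit (-2.75 ± 0.43, adjusted p = 0.00601), both lower in 4 of 4 pairs. Macrophage markers fell beside them in 3 of 8 (6 lower and 1 higher over the list alone, median -5.32, or -1.76 with bounds, adjusted p = 0.0174 and 0.45). Marco, a scavenger receptor, fell by 5.03 ± 0.71 (adjusted p = 0.00398, lower in 3 of 4 pairs and at 0 on both sides of the other). Cd163 and C1qb were at 0 in all 4 libraries with U0126, at least 10.4-fold and 3.52-fold lower. Dedifferentiation genes fell in 6 of 26 and rose in 1 (9 and 2 over the list alone, median -0.27, adjusted p = 0.002 and 0.45). S100a6 was at -1.92 ± 0.21 (adjusted p = 0.00111). ERK targets fell in 2 of 17 (3 lower and 1 higher over the list alone, median -0.14, adjusted p = 0.039 and 0.414). The ERK call was lost on TPM (adjusted p = 0.0677) and without the 2 libraries that received LY294002 with rapamycin (0.0961). Without those 2 the ERK median was further from 0, at -0.38 with 2 of 17 lower, and sterol synthesis lay at 0.52 (adjusted p = 8.82e-06). Dusp6 and Spry4, which feed back on ERK, were at -0.13 ± 0.14 (adjusted p = 0.626) and 0.17 ± 0.42 (adjusted p = 0.846).

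Albumin and the liver's master regulator did not pass with U0126: Alb was at 0.22 ± 0.22 (edgeR adjusted p = 0.593) and Hnf4a at 0.11 ± 0.16 (0.727), as were Vim at 0.44 ± 0.27 (0.364) and Cyp3a11 at 0.83 ± 0.71 (0.527). Lists not called were plasma proteins (0 higher and 1 lower of 21, median 0.161 but mean -0.000267 and camera downward, adjusted p = 0.922) and hepatocyte transcription factors (median 0.26, 0.0658). Nor were gluconeogenesis (-0.22, 0.605), TGF-beta targets (-0.51, 0.105), lipogenesis (0.45, 0.0778), FOXO targets (-0.26, 0.11), and ribosome biogenesis (-0.08, 0.331). The same held for acute phase (-0.21, 0.413), immediate early (0.31, 0.11), lysosome (0.05, 0.106), fetal liver (0.64, 0.11), complement (-0.25, 0.313), and markers of cholangiocytes (-0.88, 0.11), stellate cells (-0.26, 0.956) and endothelium (-0.57, 0.121). On TPM camera called hepatocyte transcription factors (adjusted p = 0.0382) and lipogenesis (0.0296), and without the 2 libraries that received LY294002 with rapamycin it called lipogenesis (0.0147) and cholangiocyte markers (0.0245). The count was 172 without the other inhibitors in the model, a fit that also kept fewer genes (9431). It was 193 without the rapamycin library, 177 without LY294002, 315 without U0126 with rapamycin and 225 without U0126 with LY294002. On TPM limma called 673 genes with 191 higher and 482 lower, where the median of all genes shifted by -0.165.

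**Figure D3:**
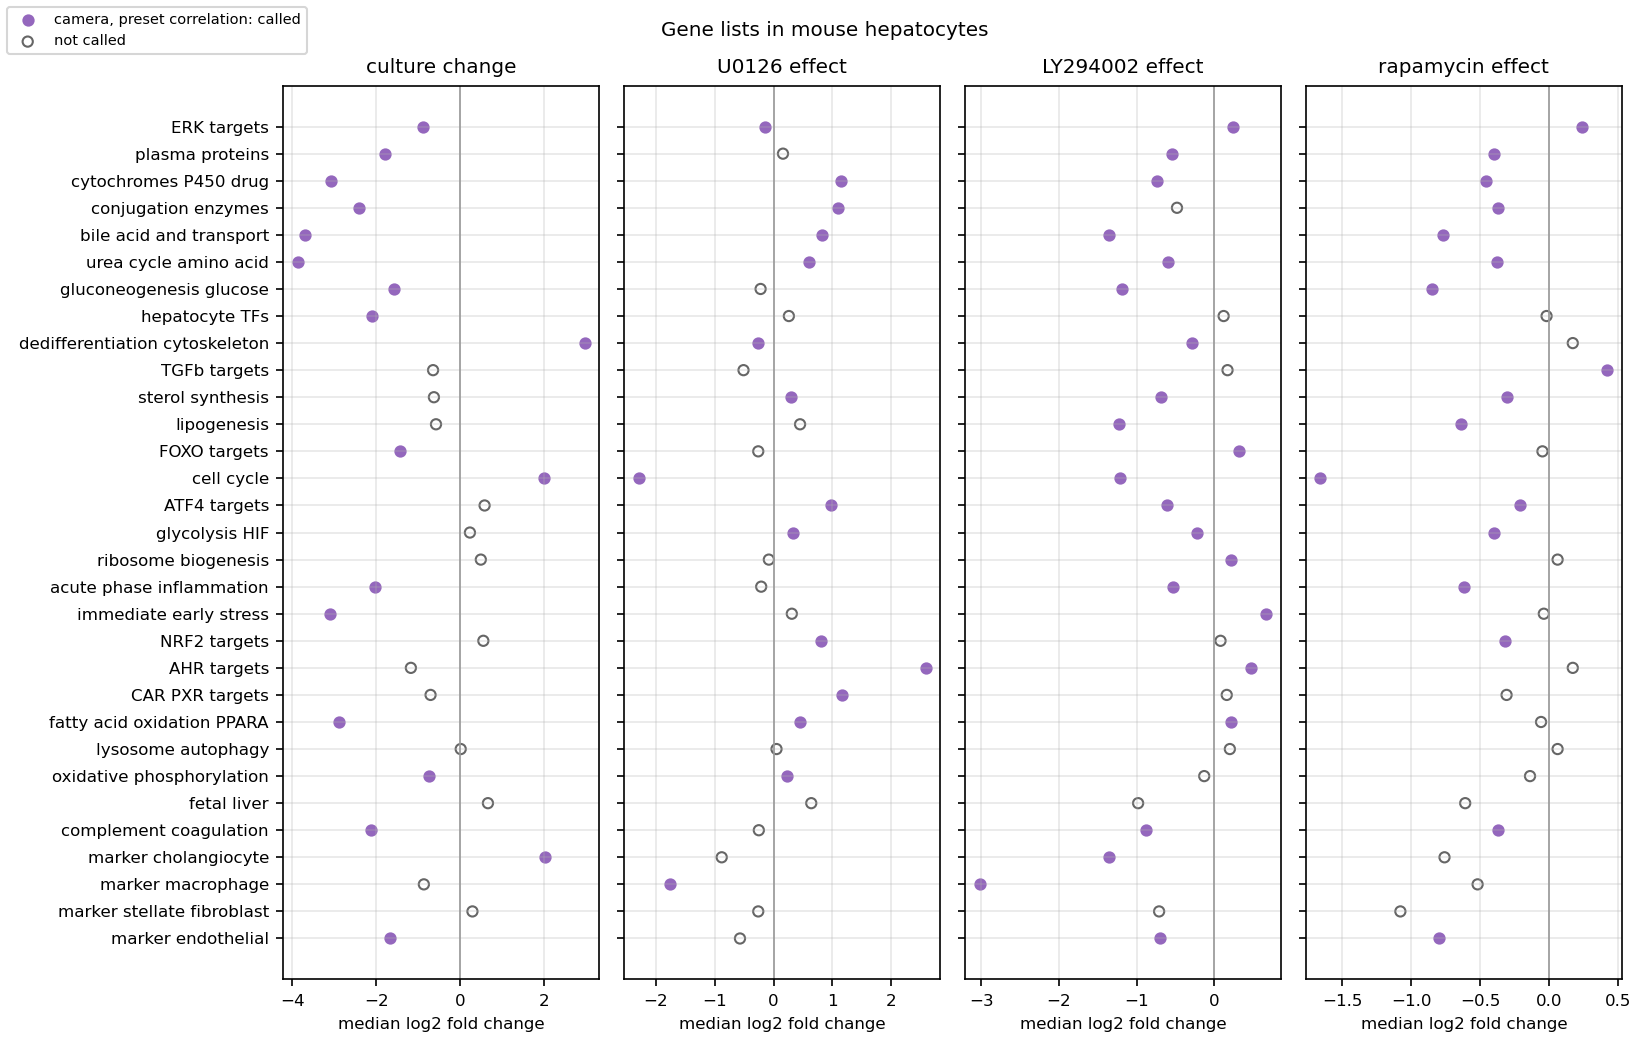
Each point is the median log2 fold change (horizontal axis) of a gene list (vertical axis) for the culture change and each inhibitor in mouse, with members at 0 in a whole group set to their bound; filled points were called by camera with its preset correlation. Cell cycle genes lay at 2.00 in culture and at -2.29, -1.21 and -1.66 with U0126, LY294002 and rapamycin, but at -0.41 with LY294002 and -0.83 with rapamycin without the 2 libraries that received both.

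LY294002 asked what blocking PI3K does. Genes of lipid synthesis, bile acid transport, glucose handling and complement fell. Scd1, the desaturase that makes monounsaturated fatty acids (chromosome 19, 44394455 to 44407879), averaged 779 ± 949 CPM with LY294002 and 4806 ± 2978 CPM without (SD, n = 4, -3.22 ± 0.44, edgeR adjusted p = 0.00539, lower in 4 of 4 matched pairs). Vil1, which encodes the microvillus protein villin (chromosome 1, 74409376 to 74435559), had the smallest adjusted p (-3.50 ± 0.20, adjusted p = 5.61e-05, 4 of 4 pairs). The cadherin gene Cdh17 was the most lowered (-5.91 ± 0.51, adjusted p = 0.00123, 4 of 4 pairs). Among raised genes Cyp1a1 led (3.05 ± 0.58, adjusted p = 0.0208), followed by Pdk4, a kinase that shuts off pyruvate oxidation (2.15 ± 0.41, adjusted p = 0.0208), both in 4 of 4 pairs. In all, 424 of 9973 genes changed, 87 higher and 337 lower.

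Lipogenic genes fell in 8 of 17 (15 adjusted over the list alone, median -1.22, camera adjusted p = 9.59e-10, and 0.339 with an estimated correlation). Among them were Thrsp of lipid synthesis (-3.25 ± 0.58, edgeR adjusted p = 0.0158) and Acaca, acetyl-CoA carboxylase (-1.34 ± 0.27). Bile acid and transport genes fell in 6 of 14 (8 over the list alone, median -1.35, adjusted p = 4.61e-05 and 0.398). Abcb11, the bile salt export pump, was at -2.05 ± 0.35 (adjusted p = 0.0134). Gluconeogenesis and glucose genes fell in 5 of 12 (9 over the list alone, median -1.19, adjusted p = 1.07e-05 and 0.339). Complement and coagulation factors fell in 9 of 23 (16 over the list alone, median -0.88, adjusted p = 4.30e-11 and 0.339), with Hc, complement C5, at -1.93 ± 0.28. ATF4 targets fell in 6 of 20 (10 over the list alone, median -0.61, adjusted p = 4.03e-07 and 0.339), with Phgdh of serine synthesis at -2.62 ± 0.37. Sterol synthesis genes (3 of 19 lower, 8 over the list alone, median -0.68, adjusted p = 3.22e-06 and 0.398), plasma proteins (5 of 21, 11, -0.55, 4.54e-05 and 0.398) and urea cycle enzymes (2 of 19, 8, -0.60, 6.56e-05 and 0.42) moved the same way. Each gene named in this paragraph was lower in 4 of 4 pairs.

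Markers of other cells fell beside these groups. Cholangiocyte markers fell in 4 of 10 (6 over the list alone, median -1.35, camera adjusted p = 4.85e-05, and 0.333 with an estimated correlation), with Krt7 at -2.16 ± 0.44. Macrophage markers fell in 1 of 8 (7 lower and 1 higher over the list alone, median -3.50, or -3.02 with bounds, adjusted p = 0.0272 and 0.442). Marco was at -6.44 ± 0.79 (edgeR adjusted p = 0.00471), and both genes were lower in 4 of 4 pairs. Endothelial markers had a median of -0.70 with 0 of 9 past edgeR's threshold (adjusted p = 0.0353 and 0.339). Cell cycle genes fell in 1 of 26 (5 over the list alone, median -1.21, adjusted p = 3.06e-06 and 0.42). Dedifferentiation genes fell in 4 of 26 (7 lower and 1 higher over the list alone, -0.29, 0.000628 and 0.42), acute phase genes in 1 of 19 with 1 higher (4 and 1 over the list alone, -0.53, 0.00951 and 0.339). Cytochromes P450 fell in 4 of 21 with 1 higher (8 and 1 over the list alone, -0.74, 0.0296 and 0.516) and glycolysis genes in 2 of 18 (4 over the list alone, -0.22, 0.0313 and 0.442). Immediate early and stress genes rose in 2 of 15 (9 over the list alone, median 0.67, adjusted p = 4.85e-05 and 0.339), with Gadd45b at 1.44 ± 0.22. FOXO targets rose in 2 of 17 (3 higher and 1 lower over the list alone, 0.32, 0.02 and 0.42), fatty acid oxidation genes in 4 of 21 (6 higher and 3 lower over the list alone, 0.22, 0.0225 and 0.339). AHR targets rose in 2 of 7 (2 over the list alone, 0.48, 0.0237 and 0.339) and ERK targets in 1 of 17 (1 over the list alone, 0.24, 0.0296 and 0.339). Ribosome biogenesis was called upward with 0 of 19 past edgeR's threshold (0.22, 0.0148 and 0.339).

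Alb was at -0.61 ± 0.22 with LY294002 (edgeR adjusted p = 0.145, lower in 4 of 4 pairs), Hnf4a at 0.12 ± 0.16 (0.728), and Dusp6 at 0.42 ± 0.14 (0.108), none past the threshold. Hepatocyte transcription factors were not called (median 0.12 but mean -0.023, camera upward, adjusted p = 0.614). Nor were conjugation enzymes (-0.48, 0.0863), TGF-beta targets (0.17, 0.372), NRF2 targets (0.08, 0.341) and CAR/PXR targets (0.17, 0.0607). The same held for oxidative phosphorylation (-0.13, 0.372), lysosome (0.20, 0.0542, but called on TPM at 0.0449), fetal liver (-0.98, 0.561) and stellate genes (-0.71, 0.215). The first principal component of the 8 cultured libraries (34% of the variance) set the 2 libraries with LY294002 and rapamycin together at 49.1 and 56.1 against -44.7 to 2.4 for the rest. Without those 2 libraries edgeR called 14 genes, all lower, 13 of which were among the 424. Camera then no longer called plasma proteins (median -0.34, adjusted p = 0.062), cytochromes P450 (-0.44, 0.0531), AHR targets (0.76, 0.0531), ERK targets (0.20, 0.135), fatty acid oxidation (0.14, 0.343) and ribosome biogenesis (0.20, 0.0531). It newly called NRF2 targets (0.10, 0.0384) and CAR/PXR targets (0.38, 0.0384) upward and oxidative phosphorylation (-0.18, 0.0384) downward. The 14 genes lay outside the sterol, lipogenesis, bile acid, gluconeogenesis and complement lists. Camera at its preset correlation still called these lists downward: gluconeogenesis (-1.39, 3.40e-06), bile acid transport (-1.02, 0.00113), lipogenesis (-0.83, 4.29e-07), complement (-0.72, 4.29e-07) and sterol synthesis (-0.34, 0.0098). An estimated correlation, with which none of these lists was called on all 8 cultured libraries, was not tried here. ATF4 targets (-0.36, 6.87e-05) and dedifferentiation genes (-0.53, 1.21e-06) were called downward too. Cell cycle genes lay at -0.39 to vehicle in the library with LY294002 alone and at -3.74 with rapamycin added. The count was 278 without the rapamycin library, 135 without LY294002, 158 without U0126 with rapamycin, 215 without U0126 with LY294002 and 121 without LY294002 with rapamycin. It was 791 by DESeq2, and 0 with edgeR without the other inhibitors in the model (1393 at an unadjusted p under 0.05). Genes called for both U0126 and LY294002 numbered 42 that rose with U0126 and fell with LY294002 (12.1 for independent lists), 32 that fell with both (11.6). A further 7 rose with both (3.1) and 5 fell with U0126 and rose with LY294002 (3.0). As both effects come from the same 8 libraries, part of the excess may come from that sharing.

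Rapamycin asked what blocking mTOR does, and 1 gene of 9973 passed. Lgals3, which encodes the lectin galectin-3 (chromosome 14, 47367751 to 47386160), fell from 76.8 ± 61.9 to 25.7 ± 19.2 CPM (SD, n = 4, -1.51 ± 0.17, edgeR adjusted p = 0.0464, lower in 4 of 4 pairs). DESeq2 called 106 genes where limma on TPM called 0 (1124 at an unadjusted p under 0.05). Cell cycle genes had a median of -1.66 with 0 of 26 past the threshold (10 lower adjusted over the list alone, camera adjusted p = 5.55e-13, and 0.364 with an estimated correlation). Lipogenic genes had one of -0.64 (8 of 17 lower over the list alone, adjusted p = 2.13e-10 and 0.364), with Scd1 at -2.42 ± 0.43 (edgeR adjusted p = 0.200). Also called downward were gluconeogenesis (-0.85, 3.35e-06 and 0.364), complement (-0.37, 7.29e-05 and 0.379) and bile acid transport (-0.77, 7.31e-05 and 0.391). Cytochromes P450 (-0.46, 0.0002 and 0.391), conjugation (-0.37, 0.000193 and 0.426), sterol synthesis (-0.32, 0.000204 and 0.426), urea cycle (-0.38, 0.000272 and 0.426) and glycolysis genes (-0.40, 0.000272 and 0.364) were too. So were plasma protein (-0.40, 0.00168 and 0.426), acute phase (-0.62, 0.00168 and 0.364), NRF2 target (-0.32, 0.00168 and 0.364), ATF4 target (-0.21, 0.00185 and 0.425) and endothelial genes (-0.80, 0.00418 and 0.364). Called upward were TGF-beta targets (0.42, 0.00168 and 0.364) and ERK targets (0.24, 0.0222 and 0.364). Over the list alone 9 of 23 complement, 4 of 12 gluconeogenesis and 3 of 17 NRF2 target genes fell. Immediate early and stress genes were not called (median -0.0397 and mean -0.229, camera upward, adjusted p = 0.734). Nor were hepatocyte transcription factors (-0.02, 0.669), dedifferentiation (0.17, 0.11), FOXO targets (-0.05, 0.734), ribosome biogenesis (0.06, 0.0758), AHR targets (0.17, 0.298), CAR/PXR targets (-0.31, 0.125) and fatty acid oxidation (-0.06, 0.651). The same held for lysosome (0.06, 0.575), oxidative phosphorylation (-0.14, 0.125) and fetal liver genes (-0.61, 0.0663), and markers of cholangiocytes (-0.76, 0.105), macrophages (-0.52, 0.486) and stellate cells (-1.08, 0.22). Without the 2 libraries that received LY294002 with rapamycin the cell cycle median was -0.83, and it was -0.48 to vehicle in the library with rapamycin alone. Camera then no longer called TGF-beta targets (median 0.32, adjusted p = 0.115), ERK targets (0.04, 0.157), complement (-0.15, 0.156), sterol synthesis (-0.01, 0.447), plasma proteins (-0.04, 0.944), NRF2 targets (-0.15, 0.253) and ATF4 targets (-0.09, 0.447). It newly called oxidative phosphorylation (-0.23, 0.00104) and fatty acid oxidation (-0.18, 0.0448) downward, and bile acid transport (-0.40, 0.00339) and acute phase genes (-0.39, 0.00185) were called nearer to 0. Alb was at -0.11 ± 0.22 (edgeR adjusted p = 0.886) and Dusp6 at -0.03 ± 0.14 (0.953). Without the 2 libraries of LY294002 with rapamycin edgeR called 0 genes (480 at an unadjusted p under 0.05), and 5 of the 8 omissions of a library also gave 0.

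The interactions asked whether an inhibitor acted differently beside another. For U0126 with LY294002 edgeR called 0 genes (551 at an unadjusted p under 0.05, 18 by DESeq2 and 0 by limma on TPM), and Cyp1a1, raised by either inhibitor, was at -3.79 ± 0.86 (adjusted p = 0.814). For U0126 with rapamycin it called 0 (240 unadjusted, 1 by DESeq2 and 0 by limma), with Thrsp of lipogenesis at 3.35 ± 0.51 (adjusted p = 0.734). For LY294002 with rapamycin it called 1 (636 unadjusted, 27 by DESeq2 and 0 by limma): Sox4, a developmental transcription factor (chromosome 13, 28948919 to 28953713), at -3.65 ± 0.37 (adjusted p = 0.0299). Sox4 passed in 1 of the 8 fits that left out a library. The interaction tests recovered 3.0% to 6.2% of simulated 2-fold changes, so few calls do not show that the inhibitors add up. Cell cycle genes lay at a median of -0.39 to vehicle with LY294002 alone, -0.48 with rapamycin alone and -3.74 with both, in 1 library each.

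Genes changed by culture were then followed under each inhibitor. With U0126, 131 of the 200 genes most lowered in culture were higher (median 0.508, camera adjusted p = 4.91e-05, and 0.328 with an estimated correlation) and 138 of the 200 most raised were lower (-0.258, 0.000114 and 0.328). With LY294002, 165 of the 200 lowered genes were lower (-0.947, 1.09e-17 and 0.237), and the raised ones lay at -0.178 (0.000605 and 0.328). With rapamycin the lowered genes lay at -0.549 (1.90e-14 and 0.237) and the raised ones at -0.045 (0.507 and 0.821). Across 9973 genes, which are not independent replicates, Pearson's r between the culture change and the inhibitor effect was -0.19 for U0126, 0.134 for LY294002 and 0.183 for rapamycin (Spearman -0.222, 0.09 and 0.174). The sign for LY294002 and rapamycin depended on the reference. With the vehicle library alone r was -0.323, -0.114 and -0.037, and with the modelled vehicle -0.358, -0.116 and -0.04, but both references also enter the inhibitor effects.

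The human mixture asked what 24 h of culture changed in PHH, with 1 library a side from different submissions, so that culture and submission cannot be told apart. Secreted and metabolic genes of the liver were lower and cytoskeletal genes higher. ADH4, an alcohol dehydrogenase, was 217-fold lower (counting interval 167 to 288) and CPS1, the first enzyme of the urea cycle, 104-fold, while TPM4, a tropomyosin, was 50.3-fold higher (40.7 to 62.9). ALB was at 0.0366 and CYP3A4 at 0.0341 of the uncultured level, and VIM was 10.9-fold higher (9.40 to 12.7). Of 10272 genes, 2243 were at least 2-fold higher and 2595 lower.

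All 20 plasma protein genes were at least 2-fold lower after 24 h (median log2 ratio -4.24, percentile 0 of matched random lists), as were 14 of 14 cytochromes P450 (-4.34), 20 of 20 conjugation enzymes (-4.73) and 23 of 23 complement and coagulation factors (-4.19). Also lower were 18 of 19 urea cycle enzymes (-4.18), 11 of 11 gluconeogenesis genes (-3.98), 12 of 14 bile acid and transport genes (-3.60), 19 of 20 fatty acid oxidation genes (-2.92), 10 of 12 CAR/PXR targets (-3.82) and 10 of 16 FOXO targets (-1.56). Markers of endothelium (7 of 8 lower, -3.52) and macrophages (11 of 16 lower and 1 higher, -1.79) were lower beside them. Hepatocyte transcription factors (11 of 16 lower, -1.64) and oxidative phosphorylation genes (18 of 19, -1.74) were lower by TMM but lay at 0.04 and -0.12 on TPM, as FOXO targets and macrophage markers lay at -0.06 and -0.14. The median of all genes lay at 1.44 on TPM, so these lists stayed below that median. HNF4A, 3.49-fold lower by TMM, was at 35.4 against 35.2 TPM. Higher were dedifferentiation genes (20 of 26, median 2.18, percentile 100), cholangiocyte markers (5 of 8, 2.19, 99.93) and NRF2 targets (7 of 13 with 3 lower, 1.15, 99.93, TXNRD1, thioredoxin reductase, 10.5-fold). So were ribosome biogenesis (9 of 20, 0.97, 99.92), ERK targets (8 of 15 with 2 lower, 1.06, 99.67) and TGF-beta targets (4 of 14 with 3 lower, 0.86, 97.84, but 87.34 on TPM). Among ERK targets FOSL1 of the AP-1 family was 78.2-fold higher (43.6 to 157) and DUSP6 1.2-fold (1.08 to 1.33). AHR targets (-1.47, percentile 3.38), sterol synthesis (-0.41, 30.8), lipogenesis (-0.89, 9.14), cell cycle (-0.07, 32.31), ATF4 targets (-0.47, 28.2), and glycolysis genes (-0.26, 59.28) lay within the range of random lists. So did acute phase (-0.33, 77.69), immediate early (0.07, 86.58), lysosome (-0.84, 4.42), fetal liver (-1.42, 20.19), stellate (0.84, 90.95), and lymphoid and erythroid genes (-1.84, 5.43). On TPM, AHR targets (percentile 0.02), lipogenesis (1.38) and lysosome genes (1.48) lay below that range. Scaled by library size, 6794 genes were higher and 884 lower with the median of all genes at 1.42, so each value holds relative to that shift.

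**Figure D4:**
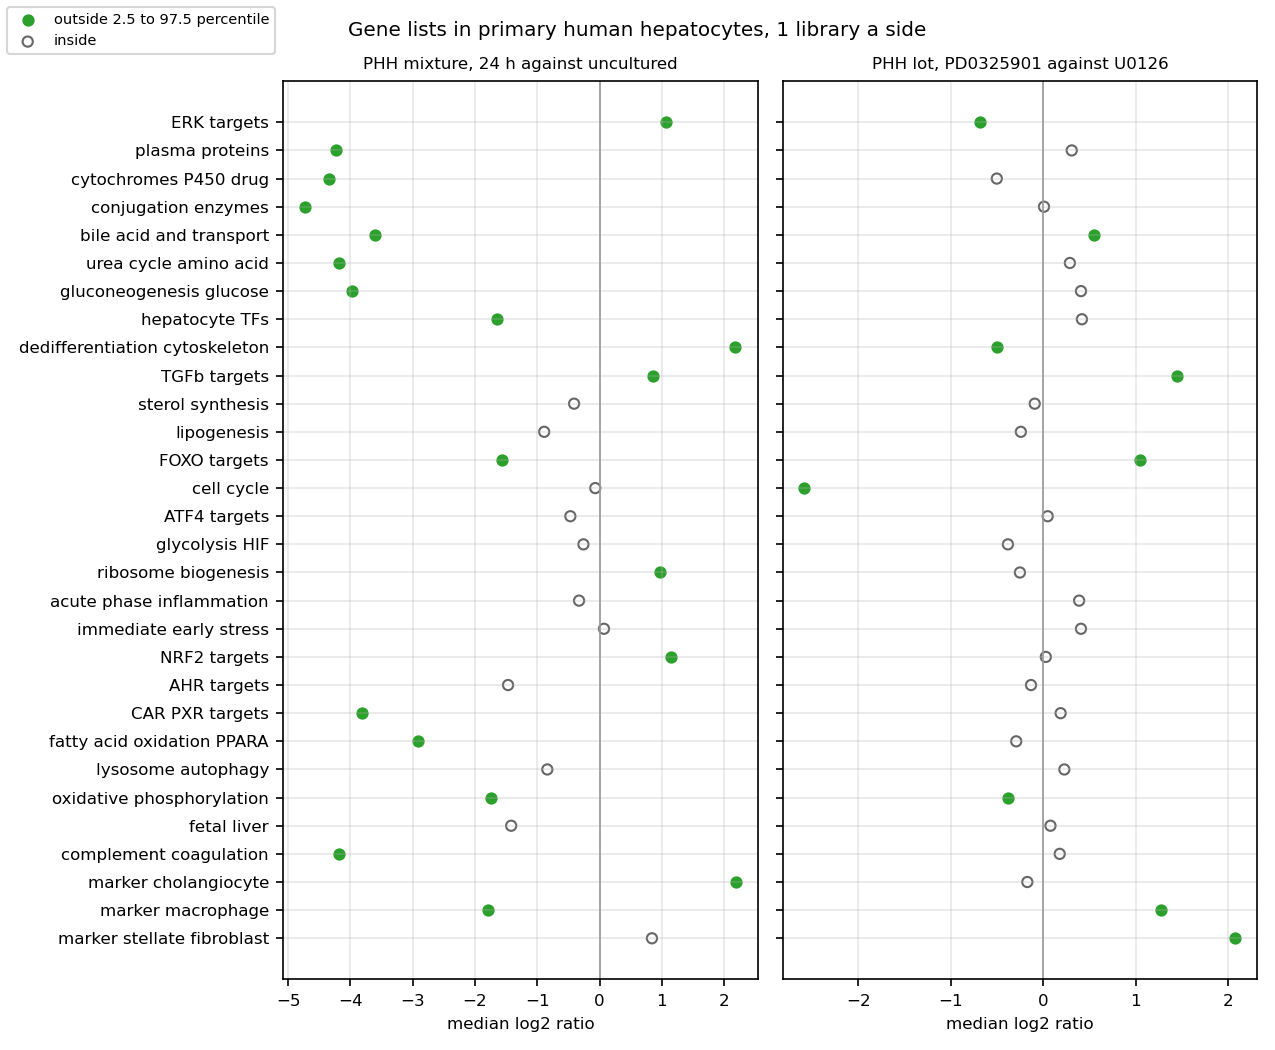
Each point is the median log2 ratio (horizontal axis) of a gene list measured in both comparisons (vertical axis), with 1 library a side; filled points lay outside the central 95% of matched random lists. Plasma protein genes lay at -4.24 after 24 h of culture, and cell cycle genes at -2.58 with PD0325901 against U0126.

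PD0325901 and U0126 both block MEK, and their PHH libraries were compared to ask where they differ, although they came from different submissions and inhibitor and submission cannot be told apart. The AHR-regulated genes CYP1A1 and CYP1A2 stood at 0.0168 (counting interval 0.00866 to 0.0295) and 0.0258 (0.0117 to 0.0493) of their level with U0126, and KRT19, a keratin of bile ducts, at 0.0294. RSAD2, IFI44L and CXCL10, which interferon is known to induce, were 217-fold (151 to 324), 120-fold (81.6 to 184) and 79.5-fold higher with PD0325901. SDS, ARG1 and TDO2 of amino acid breakdown were 10.7-fold, 8.52-fold and 7.49-fold higher, but the urea cycle and amino acid list lay inside the range of random lists (7 of 17 higher and 2 lower, median 0.29, percentile 88.68). PPARGC1A, a coactivator of gluconeogenic genes, was 11.3-fold higher.

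Cell cycle genes were lower in 26 of 26 (median -2.58, percentile 0), with PLK1, a mitotic kinase, at 0.0882 (0.0432 to 0.162). ERK targets were lower in 7 of 16 and higher in 2 (-0.68, percentile 0.6), among them DUSP6 at 0.383 (0.238 to 0.597) and FOSL1 at 0.27, whereas SPRY4 at 0.612 (0.301 to 1.18) was within counting error. Dedifferentiation genes (7 of 26 lower and 2 higher, -0.50, 0.18) and oxidative phosphorylation genes (1 of 19 lower, -0.38, 1.29) were below the random range, but not on TPM (8.55 and 14.72). TGF-beta targets (8 of 15 higher, 1.45, percentile 100) and FOXO targets (8 of 15, 1.05, 100, TXNIP, which restrains glucose uptake, 14.2-fold) were above it. So were stellate and fibroblast markers (7 of 9, 2.08, 100, COL3A1 29.3-fold), macrophage markers (3 of 4, 1.28, 99.55) and bile acid genes (4 of 14 with 3 lower, 0.55, 97.95). ALB was at 0.852, CYP3A4 at 0.462, VIM at 0.553 and HNF4A at 1.61 of the U0126 level. AHR targets as a list (-0.13, 28.59) and cytochromes P450 (-0.50, 3.49) lay inside. Plasma protein (93.74), acute phase (95.6) and immediate early genes (94.89) lay inside too, but above it on TPM (99.29, 98.61 and 98.65). In all, 1181 of 10328 genes were at least 2-fold higher and 1316 lower, and on TPM 1287 and 917.

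The remaining human comparisons, meant to show culture with vehicle and each MEK inhibitor against vehicle, each contain the library labelled PHH DMSO or that labelled HepG2 U0126. They set a library with hepatoma transcripts against a library with hepatocyte transcripts, and the cause of that was not settled. The library labelled PHH DMSO against the uncultured lot had fetal liver genes at a median of 5.90 (percentile 100) and cytochromes P450 at -9.42 (percentile 0), with 6105 of 10605 genes at least 2-fold apart, and kit and submission also differed. U0126 and PD0325901 against it had fetal liver genes at -6.83 and -6.68 (percentile 0), with 4554 of 10888 and 4979 of 10918 genes apart. The library labelled HepG2 U0126 against HepG2 DMSO had dedifferentiation genes at 3.16 (percentile 100) and fetal liver genes at -6.86, with 5753 of 10980 genes apart. The common fit of U0126 over the 4 libraries of submission 421, by their labels, called 1850 of 11516 genes in edgeR (976 higher and 874 lower, 1 residual degree of freedom). Both libraries labelled U0126 held hepatocyte transcripts and both labelled DMSO held hepatoma transcripts. The fit can therefore not be read as an effect of U0126, and its block does not take out the kind of cell. VIM led the higher genes (10.85 ± 0.77, adjusted p = 0.000672, higher in 2 of 2 pairs as labelled). ALB was at -2.70 ± 0.81 (adjusted p = 0.0561) and DUSP6 at -1.57 ± 1.58 (0.537).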

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

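Every test of an explanation in this part was chosen after the result was seen, while the splits of the libraries were planned.

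The library labelled PHH DMSO carried the hepatoma transcripts AFP and GPC3, and the library labelled HepG2 U0126 the hepatocyte transcript SAA1. RNA of hepatoma cells mixed into the first was argued against, because 144 genes abundant in the other 2 LM-Seq PHH libraries and not seen in HepG2 DMSO stood at a median ratio of 0.000766. A change made by vehicle culture cannot be told apart for the library labelled PHH DMSO, whose correlation with HepG2 DMSO exceeded that with PHH U0126 by 0.124, and would leave the other library unexplained. The PHH mixture had a Spearman correlation with the library labelled PHH DMSO of 0.625 uncultured and 0.627 after 24 h of culture. With the library labelled HepG2 U0126 it had 0.82 after 24 h. That culture was shorter and its library was made with another kit, so these values cannot decide. An exchange of the 2 labels cannot be told apart from other errors of labelling. It would have ERK targets lower in the library labelled PHH DMSO against HepG2 DMSO and in that labelled PHH U0126 against that labelled HepG2 U0126, where they lay at percentile 5.01 (median -0.19, 1 of 16 higher), inside the range of random lists. This value cannot decide against an exchange, as the ERK list lay near 0 with U0126 in mouse too (median -0.14). In the first of these pairs ERK targets lay at percentile 0, with 14 of 16 lower (median -3.60). A candidate explanation is that the library labelled PHH DMSO received a MEK inhibitor, although the different times on the 2 labels leave that open. AHR targets, which rose with U0126 in mouse, were higher in both pairs (medians 2.47 and 1.24). Cell cycle genes, which fell with U0126 in mouse, were higher in the first pair (12 of 26 with 1 lower, median 0.83). ATF4 targets, which rose in mouse, were lower there (median -1.67).

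Xenobiotic and antioxidant genes such as Cyp1a1 and Nqo1 rose with U0126 in mouse while Dusp6 and Spry4 did not pass. Reads shared between near-identical genes were argued against for the 15 AHR and NRF2 list members outside such families. These had a median log2 fold change of 0.75 (6 higher and 1 lower). The Cyp1a and Ugt1a genes of the AHR list were left out there, so this value cannot decide for Cyp1a1 and Cyp1a2. Scaling was argued against as well, since 12 of the 13 members called higher on counts were also called higher on TPM. Whether any block of MEK does this cannot be told apart from a property of U0126, because CYP1A1 and CYP1A2 with PD0325901 lay at a mean log2 ratio of -5.59 to U0126 in PHH, but in libraries of 2 submissions. These 2 genes do not stand for the whole group, as the AHR list lay inside the range of random lists there. With PD0325901 and U0126, NQO1 was at 55.1 and 49.1 TPM and TIPARP at 29.8 and 28.9 TPM, whereas CYP1B1 was at 3.56 and 31.0 TPM. A hypothesis left by these values, which was not tested, is that U0126 may act on the aryl hydrocarbon receptor apart from MEK. LY294002, an inhibitor of PI3K, raised Cyp1a1 in mouse as well.

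Cell cycle genes such as Ccnd1 and Top2a fell with U0126 together with macrophage markers such as Marco. Depth was argued against, as the libraries with U0126 held more counts than those without (log2 ratio of the means 0.125). Loss of dividing macrophages cannot be told apart from an effect in hepatocytes. The 2 libraries without U0126 that lost macrophage markers went apart, with cell cycle genes at -0.39 to vehicle with LY294002 alone and -3.74 with rapamycin added. A biological hypothesis that stays open beside it is that blocking MEK kept the cultured hepatocytes from dividing.

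Chance was argued against for U0126, where 1 of 33 splits of the 8 cultured libraries (the real one, 700 genes) gave as many genes and the highest other gave 0. The same held for LY294002 (1 of 33, with 424 genes against 0). That share, 3.03%, is the smallest these splits can give. The other splits leave the inhibitor's own effect in the residual, which can lower their counts, so chance was not excluded. For rapamycin the splits did not argue against chance (3 of 33 splits, 1 gene against at most 5). Nor did they for LY294002 with rapamycin (5 of 32, 1 gene against at most 2). The interactions of U0126 with LY294002 and with rapamycin called 0 genes by edgeR (551 and 240 at an unadjusted p under 0.05, 18 and 1 by DESeq2, 0 and 0 by limma). All 32 splits of each therefore gave as many (highest other 2 and 2), which says nothing about chance.

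The transcription factor gene Sox4 stood out because the effect of LY294002 differed with rapamycin present, by -3.65 ± 0.37 (edgeR adjusted p = 0.0299), although it passed in 1 of the 8 fits that left out a library. Among 664 mouse genes without usable counts, a signal that the comparisons did not use, limma on TPM, where the median of all genes shifted by -0.165, called 18 genes for U0126, of which Xdh, xanthine dehydrogenase, rose (1.41 ± 0.18, adjusted p = 0.00425) and 17 fell, among them Zwilch of the kinetochore (-2.14 ± 0.48, adjusted p = 0.0313). It called 6 genes for LY294002, 4 higher and 2 lower, among them the signalling gene Wnt5b (-1.37 ± 0.32, adjusted p = 0.0473), and these 3 genes were chosen after their values were seen.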

How the results depend on the processing

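Leaving out both libraries with LY294002 and rapamycin, TPM with the shifted genes, and a block for matched pairs were tests chosen after the result was seen. No replicate numbers link the libraries. With libraries matched on the other 2 inhibitors as a block, edgeR called 682 genes for U0126 (627 shared with the 700), 336 for LY294002 (326 shared with the 424) and 0 for rapamycin (1137 at an unadjusted p under 0.05). The cause was not tested for any change below except where fewer genes or libraries explain it. For U0126 the count of 700 genes was 172 without covariates and 177 to 900 with 1 library left out (193 without rapamycin, 177 without LY294002, 315 without U0126 with rapamycin, 225 without U0126 with LY294002), and 673 on TPM with 28.4% higher against 51.1%, where all genes shifted by -0.165. For LY294002 the 424 genes became 791 by DESeq2, 0 without covariates (edgeR, 1393 at an unadjusted p under 0.05), 673 with all interactions, 14 without the 2 libraries of LY294002 with rapamycin, 1048 alone against vehicle (no test) and 121 to 442 with 1 library left out (278 without rapamycin, 135 without LY294002, 158 without U0126 with rapamycin, 215 without U0126 with LY294002, 121 without LY294002 with rapamycin). For rapamycin the 1 gene became 10 without a filter, 106 by DESeq2, 0 by limma on TPM (1124 unadjusted), 0 by limma with the shifted genes (1152), 0 by edgeR without covariates (295), 73 with interactions, 0 without the 2 libraries (480), 816 alone against vehicle (no test) and 0 to 52 with 1 library left out (52 without U0126, 40 without U0126 with rapamycin, 1 without LY294002, 0 without each of the other 5). The interaction of U0126 with LY294002 gave 2 genes without a filter, 18 by DESeq2 and 0 to 1 with 1 library left out (1 without U0126 with rapamycin). That of U0126 with rapamycin gave 1, 1 and 0 to 1 (1 without U0126 with LY294002). That of LY294002 with rapamycin gave 19, 27, 0 by limma on TPM and 0 to 1 (0 without U0126, rapamycin, LY294002, U0126 with LY294002, LY294002 with rapamycin or all 3), and the 1 gene without vehicle was raised and not Sox4. The culture change gave 5937 by limma on TPM, with 84.9% higher against 47.8% and all genes shifted by 0.92, and 3061 to 4103 under the other alternatives. The common human effect gave 2850 by limma on TPM. The mixture gave 7678 by library size (88.5% higher against 46.4%), and a minimum of 20 CPM, which tests fewer genes, gave 4041 for the lot with DMSO against uncultured and 1617 for PD0325901 against U0126. With an estimated correlation camera called 0 of 31 mouse lists for U0126, 0 for LY294002, 0 for rapamycin and 0 for culture, and fry called 9, 8, 2 and 18. With the vehicle library alone as reference, which the inhibitor contrasts also use, the genes raised in culture lay at -0.308 under rapamycin, -0.700 under LY294002 (from -0.178) and -0.524 under U0126 (from -0.258), and those lowered at -0.261 under rapamycin (from -0.549) and -0.399 under LY294002 (from -0.947). The genes lowered in culture lay at 0.09 and 0.08 for PD0325901 against U0126 with 100 and 500 genes each way (from 0.27 with 200). They lay at -0.25 with 500 for the library labelled HepG2 U0126 against HepG2 DMSO (from 0.29). For PD0325901 against the library labelled PHH DMSO they lay at -1.06 and -0.83 with 100 and 500 (from -0.32). The genes raised in culture lay at 4.05 and 1.45 for U0126 against that library (from 2.91). For PD0325901 they lay at 3.84 and 1.45 (from 2.73). For that library against the uncultured lot they lay at 1.14 and 1.42 (from 2.25). Genes near 0 changed sign: with U0126 Spry4 was at -0.018 and Hnf4a at -0.079 on TPM (the same with the shifted genes), and Spry4 at -0.026 to 0.397 with 1 library left out (-0.026 without U0126 with rapamycin, -0.013 without U0126 with LY294002). With rapamycin Alb was at 0.139 without the 2 libraries, and Dusp6 at -0.108 to 0.056 with 1 library left out (0.012 without rapamycin, 0.056 without LY294002). Hnf4a in culture and HNF4A in the mixture, both lower by TMM, were at 0.065 and 0.006 on TPM. The median of all genes lay at 0.92 and 1.44 on TPM in these comparisons. At these depths a gene at 0 in a library has only a bound of 3 counts, and genes with few counts have wide intervals.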

Other observations

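Within the same treatment label, AHR targets differed between the libraries labelled PHH and those labelled HepG2. The libraries of each pair held transcripts of the same kind of cell. Their Spearman correlation was 0.881 for those labelled DMSO and 0.978 for those labelled U0126. The differences can therefore not be read as those of PHH against HepG2. In the library labelled PHH DMSO against HepG2 DMSO, CYP1A1 was 56.8-fold higher (counting interval 38.6 to 87.2), NQO1 6.22-fold (5.71 to 6.79, 4243 against 592 counts) and TIPARP, a repressor of the receptor, 5.24-fold (3.39 to 8.45), while DUSP6 stood at 0.0137 (0.00929 to 0.0195). In the library labelled PHH U0126 against that labelled HepG2 U0126, CYP1A1 was 348-fold higher (119 to 1690), CYP1A2 102-fold (43.5 to 316) and CYP1B1 10.1-fold (7.21 to 14.5), with NQO1 at 1.10 (0.927 to 1.30, 278 against 273 counts) and DUSP6 at 0.849 (0.639 to 1.13). The AHR list lay at percentile 100 of matched random lists in the first pair (4 of 6 higher and 1 lower, median log2 ratio 2.47) and at percentile 100 in the second (4 of 7 higher, median 1.24). ATF4 targets were lower (13 of 18, median -1.67, percentile 0) and cell cycle genes higher (12 of 26 with 1 lower, median 0.83, percentile 99.98) in the first pair, against -0.12 (8.83) and -0.05 (20.93) in the second. Conjugation enzymes lay at 0.08 (65.98) in the first pair and -0.24 (0.29) in the second, and urea cycle and amino acid enzymes at 0.79 (98.53) and -0.24 (1.01). Each pair has 1 library a side.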
